A study of Mus musculus with 2 samples.

How the data were processed

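Messenger RNA levels were measured on 2 Affymetrix GeneChip 3' expression arrays, 1 for mouse E14 embryonic stem cells carrying a short hairpin RNA (shRNA) against Mll2 and 1 for E14 cells carrying a control shRNA. Per the labels' protocols, the shRNAs were delivered by lentivirus for 24 h, infected cells were selected with puromycin for 5 days, and column-purified, DNase-treated total RNA was amplified into biotin-labelled cRNA. There was 1 array per group, so no difference has a replicate check, no test between the groups was possible, and no p-value is given.

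The deposited table held 45101 probe sets per array as log2 values. Per the submitters' processing notes the authors used MAS5, which combines the perfect-match and mismatch probes of a probe set into 1 signal and scales each array to a common trimmed mean. The software version and any later step are not given in the sources used here. The values were checked against this: 2 to the power of the deposited log2 values had a 2% trimmed mean of 500.0 on both arrays, and the lowest value was 0 on the log2 scale, at which 465 probe sets of the Mll2 shRNA array and 313 of the control array were listed. Detection calls were not used here. MAS5 treats every probe set alone, and mismatch subtraction makes dim probe sets noisy. The precision is limited by the number of arrays.

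The 64 control probe sets were set aside, leaving 45037. The platform annotation paired 34945 of these with 1 gene symbol and 932 with several, and 9160 were not listed in it and are unnamed here. Symbols were updated through the Entrez gene number to the RefSeq annotation of assembly GRCm38.p6 for 34741 probe sets. No name was taken from a probe set with several genes, and no coordinates are given because the table names no genome build.

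The log2 values were used as deposited. A floor was set at the 50th percentile of all values pooled over both arrays, 6.02 on the log2 scale or a signal of 64.7, and lower values were raised to it. A gene counted as measured if a probe set lay above the floor on at least 1 array, and was represented by the probe set with the highest mean value. This gave 11805 measured genes of 18193 named ones, 10682 of them above the floor on both arrays. For the other 1123, the ratio is a lower bound in size, written as "at least". Ratios are Mll2 shRNA over control shRNA on the log2 scale, and genes were counted at a ratio of 2-fold or more.

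With no replicate arrays, 2 measures of spread were used. The first was the SD of the ratio over probe sets of a gene, or, over all genes, the SD of the difference between the highest and the second probe set. The second was 1.4826 times the median absolute deviation of the ratios of the 500 genes nearest in mean level, called the spread at that level. The second measure holds real differences as well as noise, and neither covers variation between cultures.

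For 42 gene lists, the median ratio of the measured members was placed among the medians of 10000 random lists with the same number of genes in each of 20 bins of mean level. Bootstrap intervals of a median, where given, are 95% intervals from 2000 draws of its members. The percentile describes these 2 arrays and is not a p-value. A list with at least 5 measured members was said to stand apart below the 2.5th or above the 97.5th percentile. The groups, lists, floor, threshold, alternatives and the rule for named genes were fixed before the data were examined. That rule took Kmt2b and Kmt2d, the 8 genes with the largest difference in each direction among genes above the floor on both arrays, the 6 in each direction with the largest mean ratio over at least 2 probe sets, the 4 brightest bounds in each direction, and up to 4 members of each described list. A few other members are named for reference or in later tests. Most are marked as chosen after their values were seen or as outside the rule.

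The steps were tested on simulated data for this comparison, run on 11377 measured genes with noise smaller than the observed spread at each level. Changes of 3-fold and 4-fold were called in 100.0% of 50 genes each, changes of exactly 2-fold in 48.0% of 50, and 3 of 11157 unchanged genes were called. Because the noise was set below the observed spread, these shares check the steps and are not error rates of the real arrays. A list of 20 genes shifted by 0.40 lay at the 100th percentile, and 9 of 200 unchanged lists stood apart. Alternatives were median centring, quantile normalization, loess, floors at the 30th and 70th percentiles, no floor, a pseudocount equal to the floor, the mean over probe sets, leaving out probe sets with the suffixes _s_at, _x_at and _a_at, thresholds of 1.5-fold and 3-fold, lists without the members they share with other lists, and random lists not matched on level. Scaling on the bacterial spike-in controls was added after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and R 4.3.3 with limma 3.58.1 for loess, were used.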

Results

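Gene expression was compared between E14 mouse embryonic stem cells expressing an shRNA against Mll2 and E14 cells expressing a control shRNA. Mll2 is a histone H3 lysine 4 (H3K4) methyltransferase. E14 is an established embryonic stem cell line. One array was hybridised for each group. The medians of the 2 arrays were 6.01 (Mll2 shRNA) and 6.03 (control shRNA) on the log2 scale, and 49.9% and 50.1% of their probe sets lay above the floor. Across all 45037 probe sets the arrays correlated with a Pearson r of 0.93, a correlation across probe sets, which are not independent replicates. As signs of RNA quality, the 3' minus 5' difference of the Gapdh control probe sets was 0.06 in the Mll2 shRNA array and 0.05 in the control, and that of the beta-actin control probe sets was 0.77 and 0.96.

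The first question was whether the targeted transcript was lower. The name Mll2 has been used for 2 mouse genes, Kmt2d and Kmt2b, and the labels do not say which one the shRNA was designed against. Kmt2d was 2.20-fold lower in the Mll2 shRNA array, with a signal of 335 against 736 in the control (probe set 1435550_at, log2 ratio -1.14). Only 3 of the 500 genes nearest in level had a lower ratio. The other Kmt2d probe set, 1427555_at, was below the floor on both arrays, at log2 values of 4.78 and 5.40, and gave no ratio. Kmt2b had a signal of 852 in the Mll2 shRNA array and 901 in the control (1452916_at, log2 ratio -0.08), which is within the spread of 0.28 at its level and became 0.04 with spike-in scaling.

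The Kmt2d difference was the only one of at least 2-fold among the 21 measured H3K4 methyltransferases and shared subunits, in the probe set used for each gene. Men1, a subunit of some complexes of the family and named outside the rule for named genes, was at 0.12. Its second probe set, above the floor on 1 array only, gave -1.16, a lower bound in size. The list median was -0.03, at the 23.1th percentile of random lists, and 0.08 with spike-in scaling. Kmt2e, a family member with a SET domain, was higher by 0.77, and its second probe set gave 0.70. Paxip1, a subunit of the Kmt2c and Kmt2d complexes, had a ratio of -0.51, but its second probe set gave only -0.09. Kmt2c itself had a ratio of -0.36. Of 8 H3K4 demethylases, Kdm1b had the largest difference at 0.82, and the list median was 0.02 (-0.02 after loess). The 24 measured Polycomb group genes had a median of 0.06 and none reached 2-fold. Pcgf2 was at -0.72 and Bmi1, a core subunit of Polycomb repressive complex 1, at 0.65.

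Genes that differed between the arrays were then counted. Of 11805 measured genes, 173 were at least 2-fold higher and 116 at least 2-fold lower in the Mll2 shRNA array, 2.45% of those measured. The split between directions depended on the scaling. Of the differing genes 59.9% were higher as deposited, 62.0% after median centring, 51.1% after quantile normalization and 52.6% after loess. Scaling on the spike-in controls gave 260 higher and 82 lower genes, 76.0% of them higher. This scaling takes out the mean spike-in difference of -0.12, so that it raises the ratios of all genes above the floor alike. The 18 spike-in probe sets cover only the BioB, BioC, BioD and Cre controls, so they are not independent of each other. No value here measured mRNA per cell, so this scaling does not show a general rise of mRNA. In 134 of the higher and 90 of the lower genes both arrays were above the floor. The largest differences upward were in St8sia1, a sialyltransferase of ganglioside synthesis (4.85-fold), Foxa2, a transcription factor of endoderm and axial mesoderm (4.71-fold), Aard (4.16-fold), Pdk4, a kinase that inhibits pyruvate dehydrogenase (4.09-fold), Tfpi, an inhibitor of tissue factor in coagulation (3.84-fold), Vezt (3.80-fold), Notum, a secreted Wnt-inactivating enzyme (3.70-fold), and Uggt2 (3.70-fold). The spread of log2 ratios at the level of these genes ran from 0.28 for Tfpi to 0.49 for Pdk4. The control signals of Uggt2 (67.6), St8sia1 (72.9), Pdk4 (84.0) and Vezt (92.3) were close to the floor of 64.7. The sizes of these 4 differences are therefore less certain. Vezt was not borne out by its second probe set, whose log2 ratio was 0.01.

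The largest differences downward were in Arhgap8 (4.38-fold), Ebf1, a transcription factor best known from B cells (4.33-fold), 1700097N02Rik (4.22-fold), Il33, a cytokine (3.46-fold), Dab1, an adaptor of Reelin signalling (3.40-fold), Jade2 (3.39-fold), Wnt4, a secreted Wnt ligand (3.35-fold), and Pwwp2b (3.33-fold). The spread of log2 ratios at their level ran from 0.29 for Jade2 to 0.49 for Pwwp2b. The Mll2 shRNA signals of Ebf1 (81.4), Pwwp2b (89.6), Il33 (99.8) and Dab1 (101) were not far above the floor of 64.7. Of 4 measured Ebf1 probe sets only 1 was above the floor on both arrays. The log2 ratios of the others were lower bounds in size, -1.19 in the second probe set and -0.23 at the smallest. Pwwp2b had a second probe set with a log2 ratio of 0.05. Dab1 changed direction when probe sets that can detect several transcripts were left out, from -1.77 to 0.17.

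**Figure D1:**
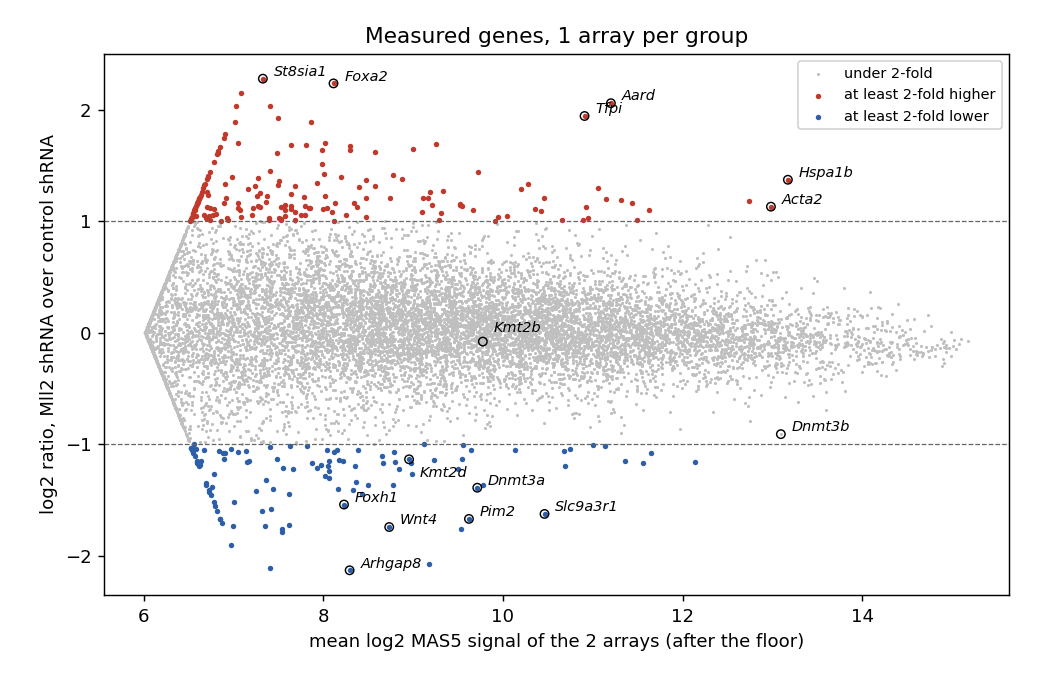
Log2 ratio of Mll2 shRNA over control shRNA (vertical axis) against the mean log2 MAS5 signal of the 2 arrays (horizontal axis) for the 11805 measured genes, 1 point per gene. Red and blue points are the 173 genes at least 2-fold higher and the 116 at least 2-fold lower, circled genes are named, and the straight edges at the left come from the floor at 6.02; Kmt2d lies at -1.14 and Kmt2b at -0.08.

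Genes with several probe sets were also ranked by their mean ratio. Averaged over the probe sets above the floor on both arrays, the log2 ratio was 1.81 ± 0.66 (SD over 2 probe sets) for St8sia1 and 1.58 ± 0.58 (SD over 4) for Tfpi. It was 1.24 ± 0.26 (SD over 3) for Cryzl1 and 1.24 ± 0.04 (SD over 2) for Mras, a Ras-family GTPase. A further Cryzl1 probe set, above the floor on 1 array only, gave 0.18, and with it the mean was 0.97. Flrt2 averaged 1.23 ± 0.48 and Slco4c1 1.23 ± 0.62 over 2 probe sets each. The lowest averages were -1.62 ± 0.11 (SD over 2) for Foxh1, the DNA-binding partner of Smad2 in Nodal signalling, -1.54 ± 0.95 (SD over 3) for 1700097N02Rik and -1.42 ± 0.46 (SD over 2) for Wnt4. Slc9a3r1, a scaffold protein of the apical membrane, averaged -1.37 ± 0.23 (SD over 3), the de novo DNA methyltransferase Dnmt3b -1.31 ± 0.56 (SD over 2), and Hopx, a homeodomain protein of heart development, -1.19 ± 0.32 (SD over 2). Some genes were above the floor on 1 array only. Of these, Zap70 was at least 4.42-fold, Zfp362 at least 4.10-fold, Apob at least 3.45-fold and Otub2 at least 3.35-fold higher. Gfod1 was at least 3.76-fold, Nt5e, the ectoenzyme CD73, at least 3.26-fold, Cysrt1 at least 3.20-fold and Sox13 at least 3.20-fold lower.

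The reliability of the counts was judged from second probe sets of the same genes. Of the 289 genes at least 2-fold apart, 92 had a second measured probe set, and in 82 of them (89.1%, 95% Wilson interval 81.1 to 94.0%) it had the same sign. It also reached 2-fold in only 20. Over 4704 genes with 2 probe sets above the floor on both arrays, the ratios of the probe sets differed with an SD of 0.37. Probe sets of a gene can share sequence and were read on the same arrays, so their agreement covers neither shared probes nor variation between cultures.

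Genes of the pluripotent state were described as a primed, a core and a naive list. The primed list, which marks the postimplantation epiblast, was lower: 13 of its 15 measured members had negative ratios, the median was -0.32, and the list lay at the lowest percentile, 0.00. The median was -0.20 with spike-in scaling and -0.68 over the 9 members in no other list. At least 2-fold lower were Pim2, a serine/threonine kinase (3.19-fold), the de novo DNA methyltransferase Dnmt3a (2.62-fold) and Pou3f1, a POU factor also called Oct6 (2.08-fold, with -0.75 in its second probe set and a mean of -0.90). Sox3 was at -0.89. No member was at least 2-fold higher. For Dnmt3a the 5 probe sets above the floor averaged -0.42 ± 0.77 (SD) and ran from -1.39 to 0.38, so that they differed in direction.

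The core pluripotency list was lower by less, with a median of -0.22 over 19 members (0.02th percentile), or -0.10 with spike-in scaling. None reached 2-fold in the probe set used. Dnmt3b was at -0.91 there and at -1.70 in its second probe set, Lin28a, an RNA-binding protein that blocks let-7 maturation, at -0.90, Fgf4 at -0.65 and Sall4 at -0.58. The 3 probe sets of Fgf4 averaged only -0.28 ± 0.39 (SD), and the second Sall4 probe set gave 0.15. The 3 best-known members, looked up after the values were seen, went in different directions: Pou5f1 (Oct4) was at -0.44, Sox2 at 0.07 and Nanog at 0.47. The naive list did not stand apart (median -0.07, 13.7th percentile, 8 members above 0 and 11 below; 0.05 with spike-in scaling). In it Dppa3 was 2.21-fold lower, whereas the LIF receptor gene Lifr was at 0.86, Prdm14, a transcription factor of the naive state and of germ cells, at 0.85, and Jam2 at 0.83. The difference between the primed and the naive list was not tested.

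**Figure D2:**
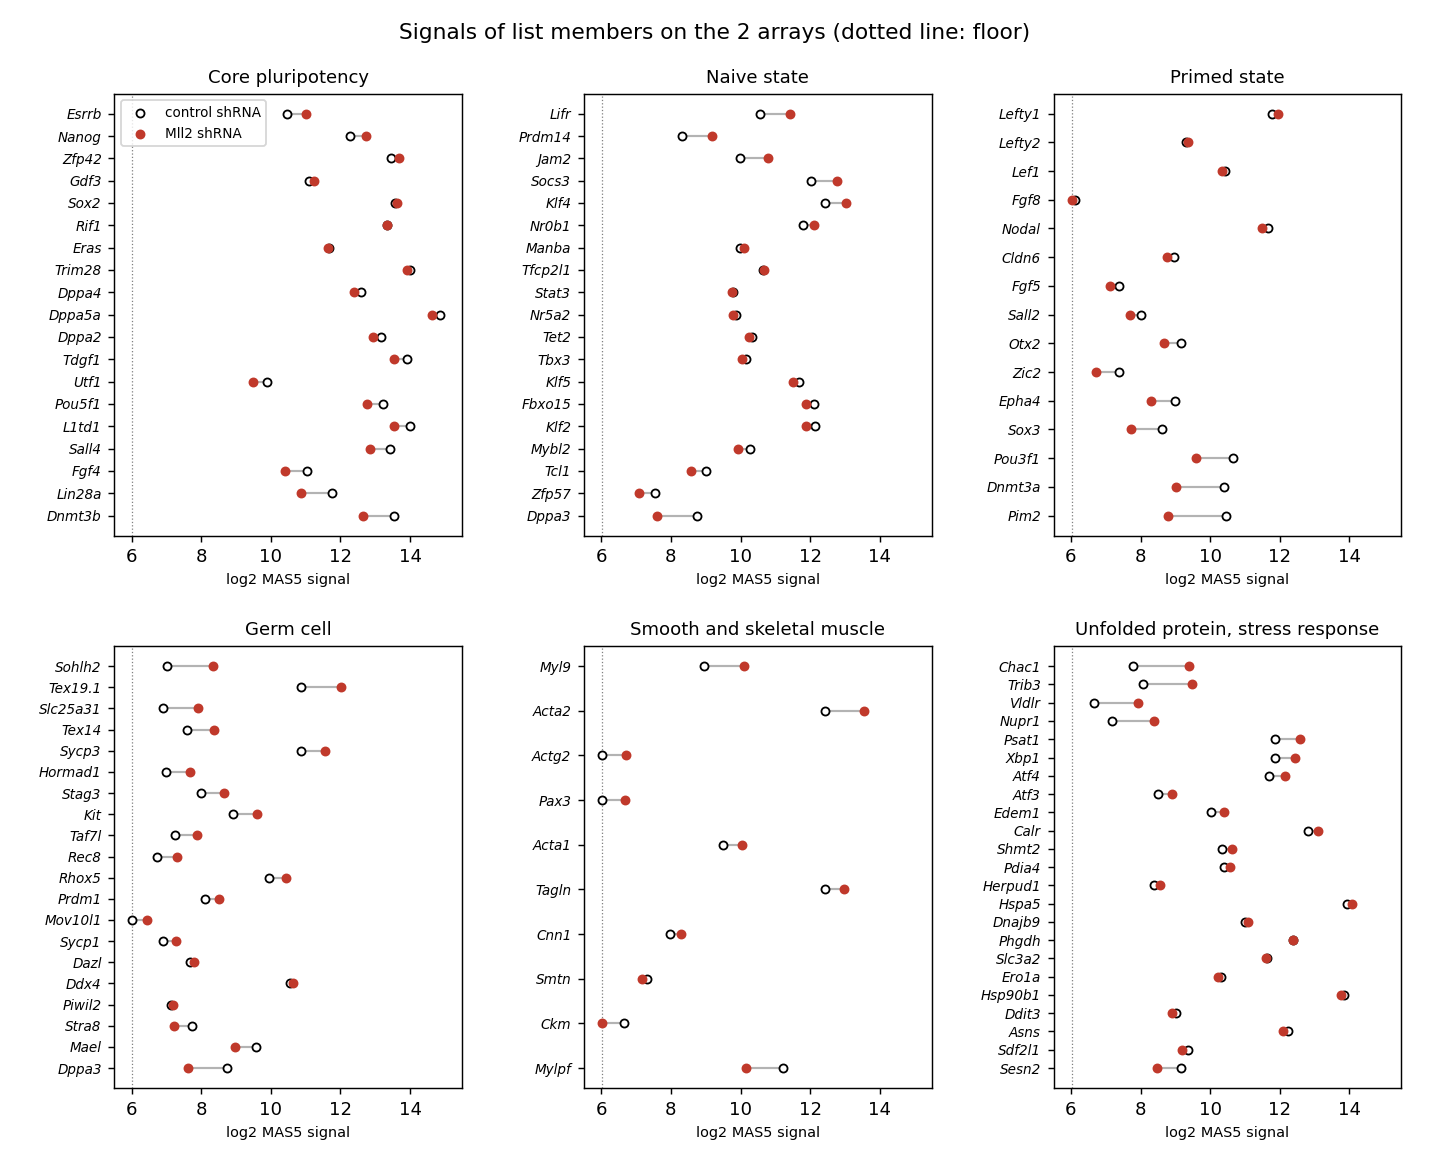
Log2 MAS5 signal (horizontal axis) of each measured member of 6 gene lists in the control shRNA array (open circles) and the Mll2 shRNA array (red circles), sorted by ratio, with values under the floor of 6.02 (dotted line) drawn at the floor. In the primed list 13 of 15 members lie to the left in the Mll2 shRNA array, and in the germ cell list 17 of 20 lie to the right.

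Lineage lists were examined for signs of differentiation, starting with the heart. Regulators of cardiac mesoderm and heart progenitors did not stand apart (median -0.11, 7.30th percentile, 19 of 31 members measured; 0.03 with spike-in scaling). Among them were 2 genes at least 2-fold lower, Foxh1 (2.91-fold) and Hopx (2.67-fold). The growth factor gene Bmp4 was at -0.84, and Smarcd3, a chromatin remodelling subunit of the heart, was at 0.62, with a spread of 0.76 at its level. None of the 14 measured sarcomere and contractile genes of the heart reached 2-fold (median 0.08, 75.1th percentile; 0.28 with spike-in scaling and -0.11 with no floor). The largest differences there were 0.95 for Ldb3, with 0.38 in its second probe set, and 0.91 for Actc1, cardiac actin, while Myl3 and Actn2 were lower by at least 1.76-fold and 1.66-fold. These 14 were of 29 in the list, and for the genes under the floor on both arrays no difference was detectable.

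Smooth and skeletal muscle genes stood apart upward (median 0.56, 99.99th percentile), with 7 of 10 measured members above 0 and 3 below. The bootstrap interval of the median over members, -0.15 to 0.84, included 0. Myl9, a myosin light chain, was 2.22-fold and Acta2, smooth muscle actin, 2.19-fold higher. Actg2 was higher by at least 1.61-fold, and the skeletal myosin light chain Mylpf was 2.09-fold lower. The other members below 0, named after their values were seen, were Ckm, lower by at least 1.55-fold, and Smtn at -0.15. Fibroblast markers, a check for feeder or stromal cells, did not stand apart (median -0.05, 21.9th percentile; 0.07 with spike-in scaling): Col5a2 was at least 2.35-fold higher, with 0.06 in its second probe set, but Col5a1 was 2.30-fold lower, with -0.40 in its second, Lox was at -0.84, and Col6a2 was lower by at least 1.66-fold, with 0.11 in its second probe set.

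Germ cell and meiosis genes had higher ratios in the Mll2 shRNA array (median 0.54, 100th percentile). Of 20 measured members 17 were above 0, and 3 reached 2-fold: Sohlh2, a germline transcription factor (2.48-fold), Tex19.1, a germline gene that restrains transposons (2.23-fold), and Slc25a31, a testis ATP/ADP carrier (2.01-fold). Dppa3, also in the naive list, was 2.21-fold lower. The retinoic acid list had the lowest median of all (-0.45, lowest percentile 0.00), with 9 of 13 members below 0 and 4 above and a bootstrap interval of -0.73 to 0.0016. Crabp2, a retinoic acid-binding protein, was at least 2.69-fold and Meis2, a homeodomain transcription factor, 2.34-fold lower, although its 4 probe sets averaged -0.83 ± 0.34 (SD). The receptor gene Rara was at -0.74 and Dhrs3 was lower by at least 1.66-fold. The receptor gene Rarb, higher by at least 1.34-fold, and Meis1, at 0.47, went the other way and were chosen after their values were seen.

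Primitive streak genes did not stand apart (median -0.10), although Foxa2 was 4.71-fold and Wnt5a 2.49-fold higher and Evx1 at least 2.16-fold lower. Mesp2 was at 0.53. The second Wnt5a probe set gave -0.34. Neuroectoderm genes lay just inside the random range (median 0.26, 96.3th percentile). Sox1, a marker of early neural progenitors, was 2.51-fold higher, and the neurofilament genes Nefm and Nefl were 3.31-fold and 2.25-fold lower. Hes5 was higher by at least 1.89-fold. Trophoblast genes had a median of -0.11 (0.0066 with spike-in scaling), with Ascl2 at least 2.05-fold lower, -0.12 in its second probe set, and Krt7 at -0.84. Primitive endoderm genes had a median of 0.03 (-0.0045 after loess) and none at 2-fold, with Nid1, a basement membrane protein, at 0.83 and Apoe at -0.63. Endothelial and blood markers had a median of 0.08, with the angiopoietin receptor gene Tek 2.19-fold higher and Esam at -0.66. Only 3 members of the list for the 2-cell-like state were measured (median 0.16), too few to place it.

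Stress and metabolism lists showed 3 further lists that stood apart. Genes of the unfolded protein and integrated stress response were higher (median 0.19, 99.7th percentile, 16 of 23 members above 0; 0.31 with spike-in scaling). The 4 members at 2-fold were Chac1, a glutathione-degrading enzyme (3.06-fold), Trib3, a pseudokinase (2.67-fold), Vldlr (2.37-fold) and Nupr1 (2.32-fold, with 0.74 in its second probe set), and no member was at least 2-fold lower. This list stood apart no longer when the probe sets with suffixes were left out (median 0.12, 82.0th percentile). Glycolysis and hypoxia genes were lower by small amounts (median -0.20, 0.15th percentile, 18 of 23 members below 0), and by less with spike-in scaling (median -0.08). None reached 2-fold, with Pfkl at -0.60 (second probe set -0.15), Aldoa at -0.54 and Pkm at -0.46, while Vegfa was at 0.71. Histone genes had the highest median (0.74, 100th percentile), but only 6 of 20 were measured. Of these, 4 were above 0, H3f3b at 0.88, H1f2 at 0.87, H2aw at 0.83 and H2ax at 0.65, and 2 below, H2az1 at -0.13 and H3f3a at -0.08. The last 2 are named outside the rule for named genes. The bootstrap interval of the median, -0.11 to 0.87, included 0. The median was 0.36 with the floor at the 70th percentile, and 7 of the 20 had a probe set that named them alone. H3f3b and H3f3a both encode the variant H3.3, and H2ax encodes the variant H2A.X.

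**Figure D3:**
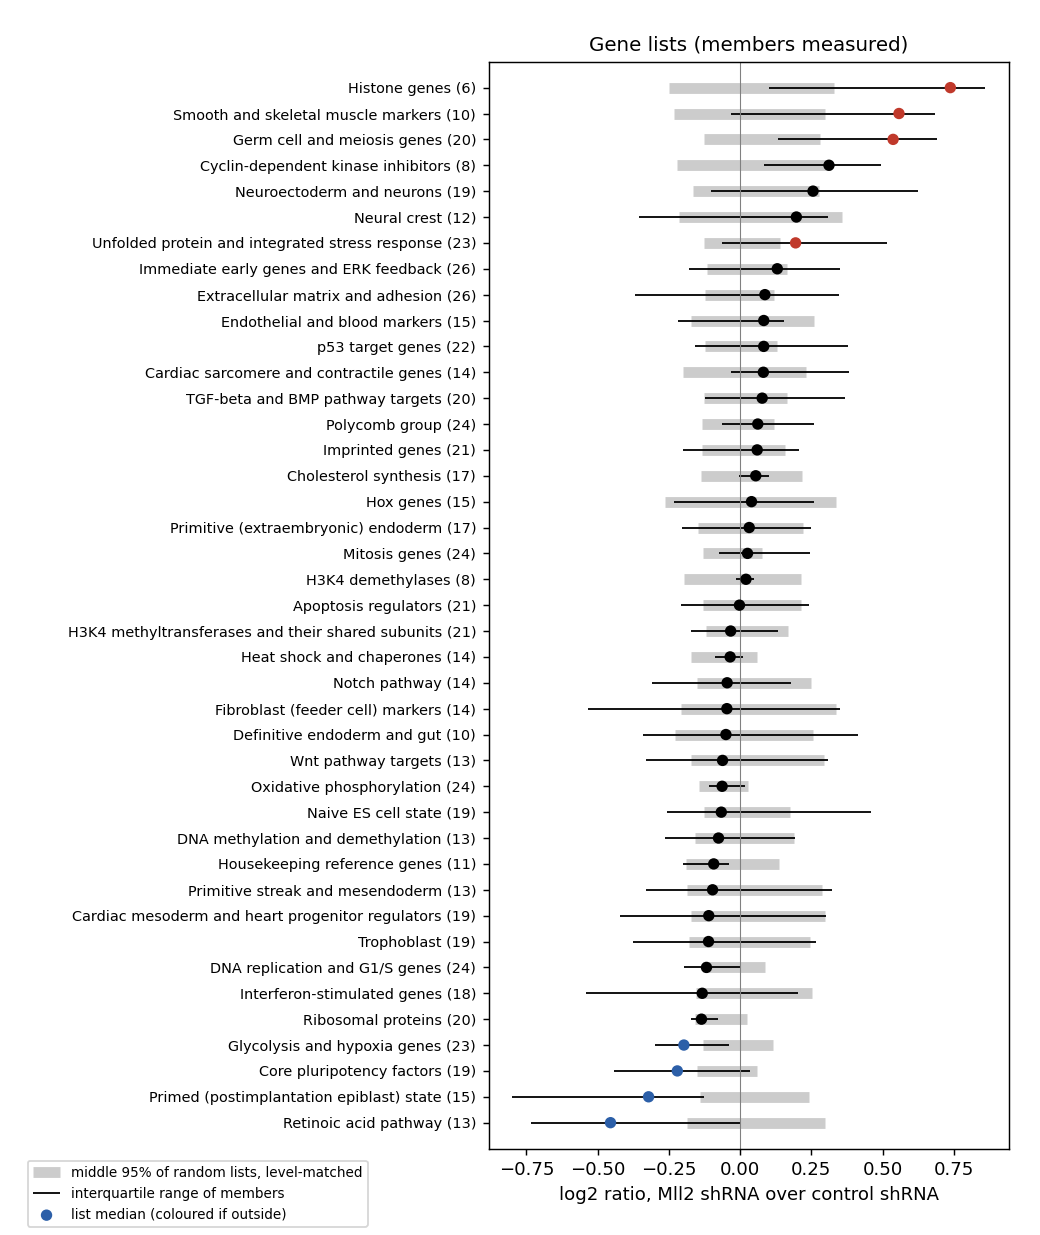
Median log2 ratio (horizontal axis) of the 41 gene lists with at least 5 measured members, with the interquartile range of the members (lines) and the middle 95% of the medians of level-matched random lists (grey bars); the number of measured members is in brackets. The 4 lists in red lie above and the 4 in blue below the grey bars. Lists of genes drawn at random would give about 2.05 of 41, which does not tell how many would stand apart between replicate cultures.

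In all, 8 of the 41 lists that could be placed stood apart, 4 in each direction. Lists share genes and were placed one by one, so these are descriptions of 2 arrays.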

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

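The test of probe-set agreement was chosen after its result was seen, and the test on scalings was written beforehand. Of the probe sets that carry no gene name here, 2603 were measured; 25 were at least 2-fold higher in the Mll2 shRNA array than in the control array, and 37 were at least 2-fold lower. They were flagged because no comparison used them. The share of unnamed probe sets at 2-fold was close to the 2.45% of measured named genes, so they did not stand out by that share. In direction they differed: more were lower than higher, whereas 173 named genes were higher and 116 lower. Among those of them above the floor on both arrays, the largest difference downward was in 1424797_a_at, 5.57-fold lower, and the largest upward in 1439881_at, 3.04-fold higher. Of the 574 measured probe sets that match several genes, 9 were at least 2-fold higher and 3 at least 2-fold lower, a share also close to that of named genes.

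The 289 genes at least 2-fold apart rest on 1 array per group. For the 92 with a second measured probe set, noise of single probe sets as the whole cause is argued against. The second had the same sign in 89.1% (interval 81.1 to 94.0%), where noise independent between probe sets would give about 50%. It reached 2-fold in only 20, and the other called genes have no such check. Dim genes weighed in the count: 112 higher and 65 lower genes lay at log2 levels of 6 to 8. Uneven scaling of the 2 arrays as the whole cause is argued against as well. Among median centring, quantile normalization and loess, 90% of the 289 genes stayed 2-fold apart in the same direction in the least favourable case. With spike-in scaling, chosen after seeing the data, 88.2% did so, but the split between directions moved to 260 higher and 82 lower. Quantile normalization and loess moved the split the other way, to 144 higher and 138 lower and to 152 and 137. What stays open is any difference between the 2 cultures that is not due to the shRNA target, such as off-target effects of the hairpin or day-to-day variation, which no value here can test.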

How the results depend on the processing

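Scaling on the spike-in controls was chosen after seeing the data. No paired analysis was possible because each group had 1 array, and for the same reason no array could be left out. The ratios of Kmt2d and Kmt2b moved by less than the spread at their level under each alternative, and Kmt2d lay between -1.20 after loess and, close to the threshold, -1.02 with spike-in scaling and -1.003 with a pseudocount. The counts depended on how dim genes were treated. With the floor at the 30th percentile 507 genes were at least 2-fold higher and 494 lower, at the 70th percentile 50 and 38, with no floor and no filter 1753 and 1744, and with a pseudocount 90 and 71. At the same settings second probe sets had the same sign in 67.4% (30th percentile), 96.7% (70th) and 55.6% (no floor) of called genes, and the SD of the difference was 0.49, 0.28 and 1.30. Thresholds of 1.5-fold and 3-fold gave 875 and 27 higher and 556 and 18 lower genes. Spike-in scaling moved the median ratio of all genes from 0.03 to 0.14 and gave 260 higher and 82 lower genes, 76.0% higher against 59.9%. Quantile normalization gave 144 higher and 138 lower genes (51.1% higher), and loess 152 and 137 (52.6% higher). The number of lists apart was 14 with the floor at the 70th percentile, where few members remained, and 7 to 11 otherwise. Newly apart at that floor were 6 lists, among them the cardiac progenitor list at -0.49, with 6 members left. Under at least 1 alternative the lists of definitive endoderm, DNA replication, Notch, primitive streak, ribosomal protein and trophoblast genes also stood apart downward. Neuroectoderm genes, cyclin-dependent kinase inhibitors and p53 targets stood apart upward under at least 1. The stress response list no longer stood apart at a median of 0.12 without suffixed probe sets, nor at 0.19 against unmatched random lists (97.1th percentile). The other 7 lists stood apart under every alternative that left at least 5 members, which leaving out suffixed probe sets did not for histones. The medians of 16 lists changed sign under at least 1 of the 4 scalings, 14 of them with spike-in scaling, and 0 of these lists stood apart. Of 1724 values of 181 genes under the alternatives, 1619 moved by less than the spread at their level and 104 by more. Among genes at least 2-fold apart 1 value reversed: Dab1, at 0.17 without suffixed probe sets. Sign changes of genes under 2-fold were not counted as reversals and are among the 1619 and 104. As the mean over probe sets, 14 of the 67 named genes at 2-fold were below it: Ascl2, Col5a1, Col5a2, Cryzl1, Dab1, Dnmt3a, Etv4, Hoxa9, Meis2, Nupr1, Pou3f1, Pwwp2b, Vezt and Wnt5a. The cause of these changes was not tested beyond the number of genes each setting admits. Dim genes had less certain ratios: the spread was 0.43 at log2 levels of 6 to 8 and 0.11 at 14 to 16.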

Other observations

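The test on fibroblasts was chosen after its result was seen, in place of a comparison of signal gains, which set levels of different probe sets against each other. Several groups outside the lists that stood apart held single genes with clear differences. Among adhesion genes (median 0.09 over 26 members) the N-cadherin gene Cdh2 was 2.28-fold higher, with 0.83 in its second probe set, while the P-cadherin gene Cdh3 was lower by at least 1.96-fold. Krt19 was at -0.65 and the secreted matricellular gene Ccn1 at 0.69, with a mean of 1.14 over its 4 probe sets. Immediate early genes had a median of 0.13, with Jun 2.44-fold higher and the ETS factor gene Etv4 2.28-fold lower (-0.77 in its second probe set). Egr2 was higher by at least 1.94-fold, but its other probe set, above the floor on both arrays, gave 0.04, and Fos was at 0.68. The heat shock list had a median of -0.03, yet the inducible Hsp70 genes Hspa1b and Hspa1a were at 1.37 and 0.93. They are near-identical copies, so their signals cannot be assigned with certainty. In the interferon list (median -0.13, 4.05th percentile) Oas1a was 2.86-fold and Ddx58, which encodes the RNA sensor RIG-I, 2.57-fold lower, Psmb8 was at -0.81, and no member was at least 2-fold higher.

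Signalling and growth lists gave the following medians. Wnt targets had -0.06, with Notum 3.70-fold higher and Tnfrsf19 2.25-fold lower. Notch genes had -0.05, with the ligand gene Dll1 2.33-fold lower and Hes1 at 0.93. TGF-beta and BMP targets had 0.08, with Ccn2 at 0.65. DNA methylation genes had -0.08, with Dnmt3a and Dnmt3b at -1.39 and -0.91. Imprinted genes had 0.06, with Phlda2 2.23-fold lower and Sgce at 0.93. Cyclin-dependent kinase inhibitors had 0.31 (97.3th percentile), led by Cdkn1b at 0.91, which encodes p27. The p53 targets had 0.08, led by Btg2 at 0.91. DNA replication genes had -0.12, mitosis genes 0.03, apoptosis regulators -0.0021 (with Casp9 2.61-fold higher), oxidative phosphorylation -0.06, cholesterol synthesis 0.05, definitive endoderm -0.05, neural crest 0.20 (with Ngfr 2.34-fold lower), Hox genes 0.04 (with Hoxa9 at least 3.09-fold higher, and 0.37 in its second probe set) and housekeeping genes -0.09. With spike-in scaling several medians turned positive: interferon 0.01, heat shock 0.08, Wnt 0.06, Notch 0.04, DNA methylation 0.04, apoptosis 0.12, oxidative phosphorylation 0.05, definitive endoderm 0.07 and housekeeping 0.02. All 20 ribosomal protein genes had negative ratios with a median of -0.14. Their median was -0.01 after quantile normalization, and 17 of 18 bacterial spike-in probe sets were lower in the Mll2 shRNA array as well (mean -0.12 ± 0.06, SD).

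The germ cell list was higher in the Mll2 shRNA array. A level-dependent bias of the ratios is argued against, because the median was still 0.50 after loess, which takes out a trend with level. The list also lay at the 100th percentile after loess. That percentile adds little, since the random lists were matched on level from the start. A hypothesis is that germline genes were higher as a class. In a new list of 54 other germline genes, 20 were measured, and their median of 0.14 lay at the 84.5th percentile, which leaves this open: 1 of the 20, Tex11, was at least 2-fold higher and 9 were below 0.

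The muscle and contractile list was also higher, and a level-dependent bias is again argued against by a median of 0.56 after loess. Its 100th percentile after loess again adds little to the level-matched placing. Fibroblasts in the Mll2 shRNA culture stay open: of the collagen genes they express abundantly, Col1a2 was at 0.70, Col3a1 at 0.34, the median of the 3, and Col1a1 lower by at least 1.49-fold, against 1.13 for Acta2 and 0.55 for Tagln. Values that go against fibroblasts are the second probe sets of Col1a1 (0.0036) and Col3a1 (0.08) and Sparc at -0.57, but the ratios of the fibroblast markers spread too widely to exclude them. A hypothesis is that targets of the actin-regulated transcription factor SRF and its MRTF coactivators were higher in general. The 36 measured targets that were in none of the fixed lists had a median of 0.04 at the 90.5th percentile, none at 2-fold. Of them 19 were above 0 and 17 below, and the bootstrap interval of the median was -0.11 to 0.14. On these arrays the targets were thus not higher in general by as much as the muscle list, whose median was 0.56. A smaller general rise is neither borne out nor excluded.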
